A study of Danio rerio with 3 samples.

How the data were processed

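Gene expression was compared between 2 populations of FACS-sorted zebrafish (Danio rerio) kidney cells on 3 two-colour Agilent microarrays. Per the labels, each array carried cDNA of cells sorted by the marker cdh17, called renal distal tubule cells, in the Cy3 channel and cDNA of cells sorted by the marker lhx1a, called nephrogenic stem cells, in the Cy5 channel. Per the labels' protocols, about 4000 sorted cells were lysed in SuperAmp lysis buffer, their mRNA was turned into cDNA and amplified by a global PCR, and 250 ng of cDNA was labelled. The dyes had the same orientation on all 3 arrays, so an effect of dye on a single probe could not be separated from a difference between the populations. The labels call the 3 arrays biological replicates and do not say from which animals the cells came. The p-values of single probes and genes measure the spread between these 3 arrays. Per the file headers, all 3 arrays came from 1 slide, so slide could not be a batch within the comparison.

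Per the file headers, the deposited values were made with Agilent Feature Extraction 10.5.1.1, and the array design names the Zv7 (danRer5) genome build. The submitters' processing notes name Agilent Feature Extraction and affy without giving their roles. The deposited intensity values are the mean spot signal and the median local background of each channel as scanned. The deposited LogRatio values are log10 of Cy5 over Cy3 after background subtraction, detrending and dye normalization by the scanner software, per the file headers. The deposited flags mark control spots, spots well above background, saturated spots and outlier spots.

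Intensities were analysed in R 4.3.3 with limma 3.58.1, with files read by the data.table package (1.17.8) and figures drawn with matplotlib 3.10.9 under Python 3.11.15. Background was corrected with normexp (offset 50) on all spots, and log ratios were normalized by loess within each array with control spots at weight 0. Control spots were then left out, as were 48 spots with any of 4 outlier flags. No spot was saturated (0 spots), and spots of the same probe were averaged. Of the 45220 spots, 43803 were not controls and held 43603 probes. Of these probes, 24940 were well above background in the same channel on at least 2 of the 3 arrays and were tested, and 18663 dimmer probes were left out. The offset compresses ratios of dim probes toward 0. Ratios are log2 of lhx1a-labelled over cdh17-labelled cells, so a positive value is higher in the lhx1a-labelled cells.

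Probes were named through the accessions of the array design, matched without versions to a RefSeq gene table of the GRCz12tu assembly. Of the probes, 16356 were matched by accession, 1565 by symbol and 1315 by synonym, and 24367 kept the name in the deposited files. Gene names of replicate 3 were used because 11 gene names had turned into dates in the files of replicates 1 and 2. In all, 18101 probes had a gene symbol, for 12013 genes. A gene was represented by its tested probe of highest mean log2 intensity, which gave 8190 genes. Of 2091 genes with several tested probes, 997 had a probe of opposite sign. Coordinates are those of the probes on Zv7 as the files give them; no annotation of that build was used here, so exon and UTR positions were not assigned.

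The mean log2 ratio over the 3 arrays was tested against 0 with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The array was the block, since both populations of a replicate were hybridised together. Gene lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over 22 lists. Camera at the preset correlation compares the genes of a list with the other genes, so its p-values do not measure the spread between arrays. At an estimated correlation camera has few degrees of freedom with 3 arrays, so a list that it does not call may still be shifted. The lists were drawn from general knowledge of the kidney and the cells around it, and 229 of their 918 genes were not matched to the array. They cover nephron progenitor regulators, the Wnt, Notch and FGF pathways, distal and proximal tubule, podocytes, multiciliated cells, epithelial junctions, stroma, endothelium, erythroid, myeloid, lymphoid and pan-leukocyte genes, interrenal, chromaffin and Stannius cells, cell cycle, immediate early and stress genes, oxidative phosphorylation, V-ATPase, ribosomal proteins and hox genes. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined.

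The rule named lhx1a and cdh17. It then named the 10 genes each way with the largest moderated t, reported as not past the threshold where no gene passed, with the same sign on all 3 arrays, well above background in both channels on at least 2 arrays and with a gene symbol. It also named up to 5 genes per direction with the largest bound among genes detected in 1 population only, and up to 4 examples per list with the smallest adjusted p, some of which are not reported here. A probe counted as detected in 1 population when it was well above background on all 3 arrays in that channel and on none in the other. Its bound is the mean log2 signal of the bright channel minus that of the dim channel, where the dim signal on each array is at least the lowest signal among probes well above background. These signals were taken per channel after loess and Aquantile normalization, and remain open to dye bias without a dye swap.

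The fit was tested on simulated log ratios for the comparison of lhx1a and cdh17 cells, with the spread of the 24920 probes measured on every array. With 100 probes changed by 2 on the log2 scale, 0% were recovered at the measured spread and 91% at 0.1 of it. With 100 probes changed by 4, 34% were recovered at the measured spread and 98% at 0.1 of it. Unchanged probes gave 2 false calls at the measured spread and 10 at 0.1 of it. In simulated lists of 30 of 8184 uncorrelated genes, camera gave an unadjusted p under 0.05 for 100% of 100 lists shifted by 1 and for 2% of 100 lists that were not shifted. Correlated genes were not simulated. In the data the estimated correlation was 0.086 for the stress list, 0.171 for the myeloid list and 0.019 for the multiciliated list.

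Alternatives covered the normexp offset, no background correction, the scanner software's log ratio, median centring instead of loess, no filter or a stricter filter on dim probes, outlier spots kept, array weights, an intensity trend with a robust prior, scaling between arrays, the 6 channels as 3 against 3 samples with no replicate block, each replicate left out, the mean of all probes of a gene, an estimated inter-gene correlation and a 2-fold minimum. For lists, the trend and robust prior entered through the moderated statistics. The number of arrays limits the precision.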

Results

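The data set holds 3 two-colour arrays that set lhx1a-sorted cells, labelled nephrogenic stem cells, beside cdh17-sorted cells, labelled renal distal tubule cells, in 3 replicates. The lhx1a gene encodes a LIM homeodomain transcription factor of early nephrons, and cdh17 encodes a cadherin of tubule epithelium. In the Cy3 channel of the cdh17-labelled cells, 18381, 18962 and 17013 probes were well above background in replicates 1, 2 and 3. In the Cy5 channel of the lhx1a-labelled cells the numbers were 23591, 25855 and 25066. Median signals were 26.1, 25.7 and 24.6 over backgrounds of 14, 14 and 14.5 in Cy3, and 83.0, 92.4 and 92.1 over 49, 50 and 51 in Cy5.

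The genes used for the sorts did not separate the populations. The lhx1a log2 ratio of lhx1a-labelled over cdh17-labelled cells was -0.68, 0.19 and -2.94 on the 3 arrays, against the direction of the label on 2 of 3. Its mean was -1.14 ± 0.77 (SE, n = 3; limma adjusted p = 0.711). The cdh17 log2 ratio was 0.75, -2.15 and 0.21, with a mean of -0.40 ± 0.73 (SE, n = 3; limma adjusted p = 0.836). Another cdh17 probe was left out as dim, being well above background on 1 array in each channel. Its log2 ratios were -3.46, 0.19 and -0.16, with a mean of -1.145. The lhx1a probe lies on Zv7 chromosome 15 from 26844303 to 26844362 and the tested cdh17 probe on chromosome 16 from 19727204 to 19727263. Neither mean differed from 0 by more than the spread between arrays, so the populations are called lhx1a-labelled and cdh17-labelled cells, and every direction below rests on the labels. With median centring in place of loess, which raised the median of all tested genes from 0.007 to 0.55, the means were 0.56 for lhx1a and 1.24 for cdh17, and without replicate 2 the cdh17 mean was 0.48.

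**Figure D1:**
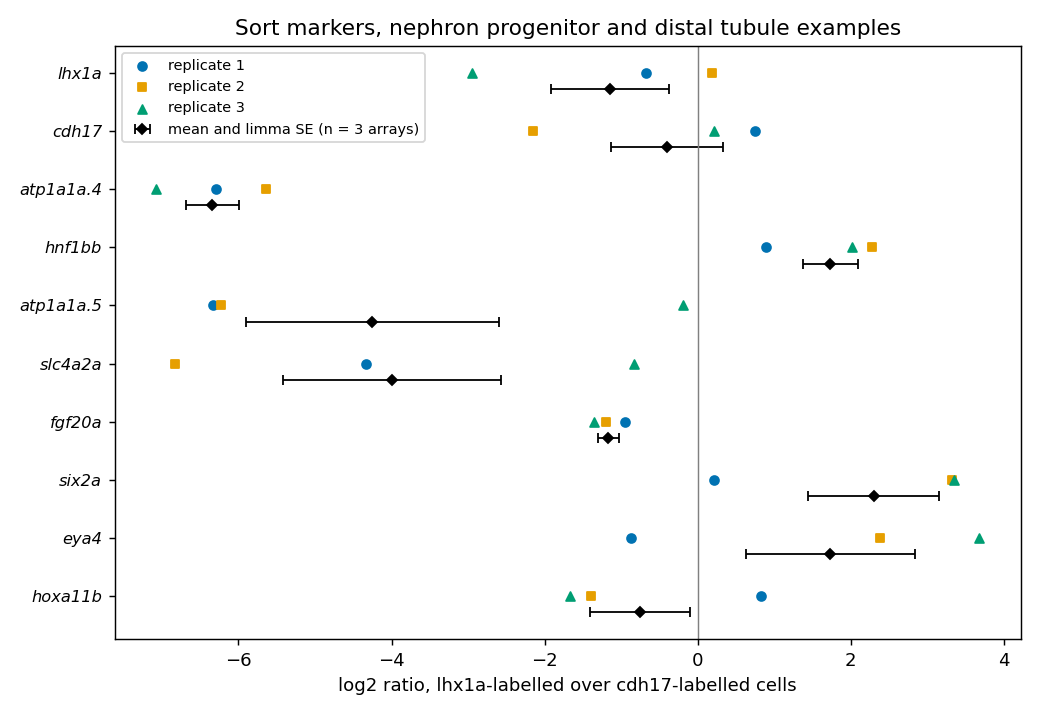
Log2 ratio of lhx1a-labelled over cdh17-labelled cells (x axis) for the sort markers and the examples of the distal tubule and nephron progenitor lists (y axis). Coloured points are the 3 arrays and black diamonds the mean with limma's SE; atp1a1a.4 lies between -7.08 and -5.64 on all 3 arrays, while lhx1a and cdh17 lie on both sides of 0.

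Of the 10 genes higher in lhx1a-labelled cells with the largest moderated t, 4 were on the immediate early and stress list: dnajb1b, nr4a1, hsp70l and hsp90aa1.2. The mean log2 ratio of f3b, a tissue factor that starts coagulation, was 5.90 ± 0.26 (SE, n = 3), a 59.6-fold ratio, with limma adjusted p = 0.485. For the heat-inducible chaperone hsp70l it was 5.76 ± 0.38, for its co-chaperone dnajb1b 4.54 ± 0.23, for hsp90aa1.2 4.07 ± 0.34 and for the early response nuclear receptor nr4a1 4.58 ± 0.30. On the side of the cdh17-labelled cells, atp1a1a.4, a sodium pump alpha subunit, had a mean of -6.34 ± 0.35, an 81.0-fold ratio, and ND6, a mitochondrial subunit of complex I, had -3.07 ± 0.22. None of these passed the threshold: the limma adjusted p was 0.538 for each of them except f3b.

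The rest of the 10 genes higher in lhx1a-labelled cells by moderated t were hnrnpa0l at 4.93 ± 0.41, the RNA helicase ddx5 at 3.48 ± 0.23, the lysosomal transporter slc17a5 at 2.88 ± 0.18, the helix-loop-helix inhibitor id1 at 2.81 ± 0.20 and the transcription factor mef2ca at 1.34 ± 0.11. The rest of the 10 lower genes were casd1 at -2.93 ± 0.14, the mitochondrial ADP/ATP carrier slc25a5 at -2.00 ± 0.17, the proteasome subunit psmd6 at -1.86 ± 0.15, the prohibitin phb2a at -1.82 ± 0.11, adgrv1 at -1.55 ± 0.14, the splicing factor txnl4a at -1.46 ± 0.12, the mitochondrial import subunit tomm7 at -1.31 ± 0.13 and pleckstrin, plek, at -1.21 ± 0.11. These genes too were not past the threshold, each with a limma adjusted p = 0.538. The casd1 value rests on its brightest probe, and 2 of its other probes had the opposite sign, as had 1 of txnl4a. The atp1a1a and hsp70 genes have close copies, and which copies their probes detect is uncertain. With median centring the means of phb2a, psmd6, slc25a5 and adgrv1 lay above 0, at 0.065, 0.058, 0.79 and 0.068, where the median of all tested genes was 0.55.

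**Figure D2:**
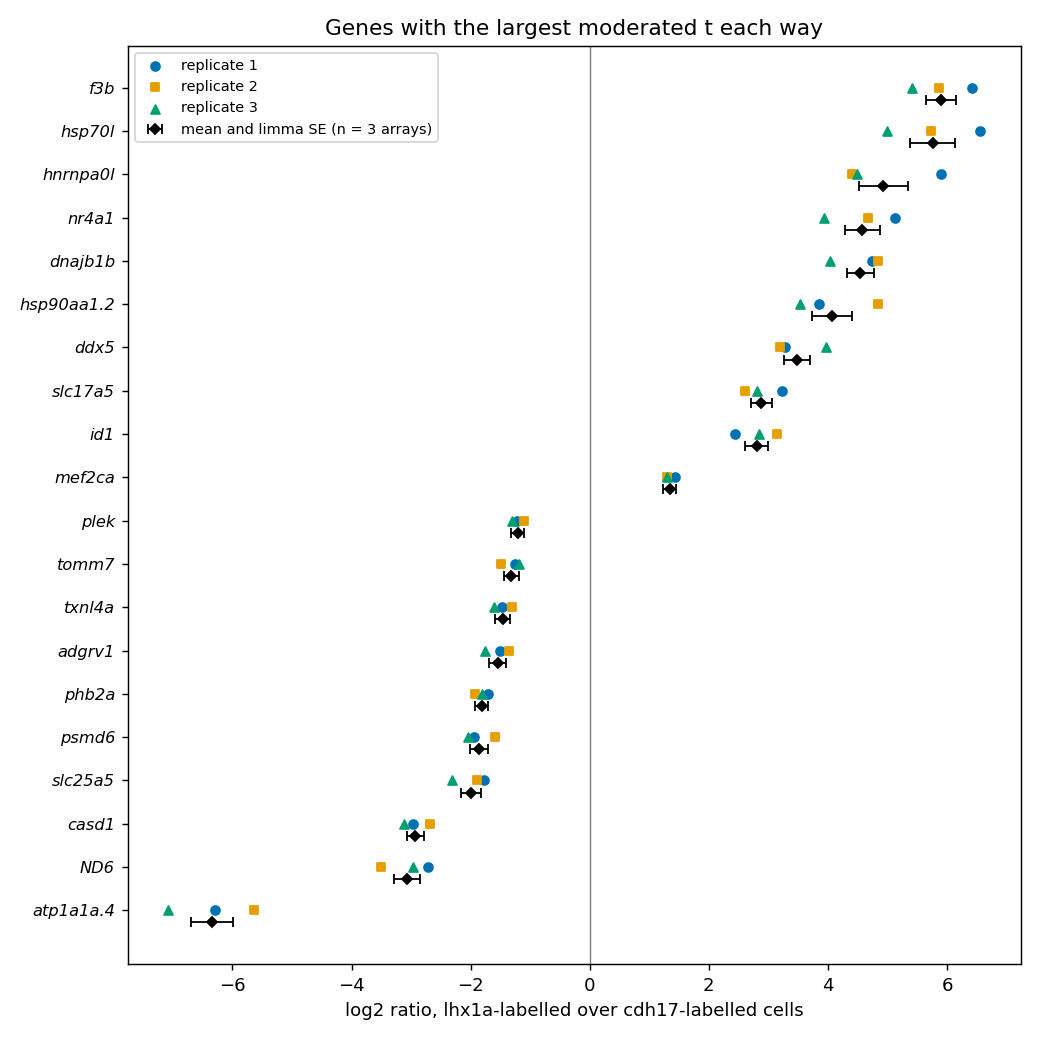
Log2 ratio of lhx1a-labelled over cdh17-labelled cells (x axis) for the 10 genes each way with the largest moderated t (y axis). Coloured points are the 3 arrays and black diamonds the mean with limma's SE; f3b lies between 5.42 and 6.42 and atp1a1a.4 between -7.08 and -5.64, and none of the genes passed the threshold.

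Over all genes, limma called 0 of 24940 probes and 0 of 8190 genes at an adjusted p under 0.05, and the lowest adjusted p was 0.485. At an unadjusted p under 0.05 it gave 1599 probes and 553 genes, 277 higher and 276 lower. By chance 410 genes would be expected if the p-values were evenly spread. With the sign of replicate 1, 2 or 3 turned, limma gave 199, 160 and 154 genes, so 410 may not be the chance level here. The count of genes past the adjusted threshold stayed at 0 under all 16 alternatives, with 411 to 1956 genes at an unadjusted p under 0.05. For the 2-fold minimum this was fixed in advance, since it can only remove genes that the main fit called. Log ratios of the arrays correlated weakly over genes, with Pearson's r of 0.09, 0.07 and 0.115 for the pairs 1 and 2, 1 and 3, and 2 and 3; genes are not independent replicates. On single arrays, 1808, 1993 and 1676 genes lay beyond 2-fold, and 99 were higher and 60 lower by at least 2-fold on all 3. That count was added after the data were seen, and its total of 159 ran from 126 to 905 over the alternatives.

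The immediate early and stress genes were higher in lhx1a-labelled cells as a group. Of 49 tested members 42 had a mean above 0 and 16 were over 2-fold higher on all 3 arrays, with a median log2 ratio of 2.09 and array medians of 0.51, 3.51 and 2.76. The jun transcription factor had a mean of 4.88 ± 0.47, the survival factor mcl1a 5.77 ± 0.58, hsp70l 5.76 ± 0.38 and nr4a1 4.58 ± 0.30. Over all probes 0 members were past the limma threshold, and 12 were higher and 0 lower when adjusted over the list alone. Camera with the preset correlation gave an adjusted p = 3.8e-12 from limma's log ratios. The call was lost with other tests. Camera with an estimated correlation gave p = 0.0581 (adjusted p = 0.826), and fry gave p = 0.0139 (adjusted p = 0.305). Several lists shared the adjusted p of 0.826 from camera, so it does not measure this list alone. Over the alternatives the median ran from 1.40 to 4.18, the highest with median centring.

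Myeloid genes were also higher as a group by camera at the preset correlation (adjusted p = 8.46e-05, limma). Camera with an estimated correlation gave p = 0.172 (adjusted p = 0.826). Of 30 tested members 24 had a mean above 0, the median log2 ratio was 1.04, and the array medians were 0.52, 2.36 and 0.12. The examples were nccrp1 at 5.20 ± 0.53, the mast cell protease cpa5 at 4.88 ± 0.66, the collagenase mmp13a at 4.22 ± 0.68 and the phagocyte oxidase subunit ncf4 at 1.39 ± 0.19. Members past the limma threshold were 0 over all probes and 0 when adjusted over the list alone. Without replicate 2 the median was 0.58 and without replicate 1 it was 1.56. With median centring camera's adjusted p was 0.0868, within 2.32e-06 to 0.826 over all alternatives. The other leukocyte lists were not shifted by camera: the pan-leukocyte list had a median of -0.003 over 15 genes (camera adjusted p = 0.883) and the lymphoid list -0.12 over 18 (0.472). In the pan-leukocyte list plek was the 1 gene past limma when adjusted over the list alone (adjusted p = 0.0240), at -1.21 ± 0.11, and 0 passed over all probes.

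Genes of multiciliated cells were lower in lhx1a-labelled cells as a group by camera (adjusted p = 0.00174, limma). Camera with an estimated correlation gave p = 0.0778 (adjusted p = 0.826). Of 29 tested members 24 had a mean below 0, with a median of -0.74 and array medians of -0.31, -0.41 and -0.21. The ciliary regulator foxj1b had a mean of -4.16 ± 1.90, cimap1b -4.91 ± 1.99 and the axoneme protein spag6 -3.55 ± 1.78. Members past limma were 0 over all probes and 0 when adjusted over the list alone. The median was -0.41 without replicate 1 and -0.17 without replicate 2, and over all alternatives it ran from -1.35 to -0.13.

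Distal tubule transport genes, the group the cdh17 label names, had a median of -0.40 over 33 genes, with 24 below 0 (camera adjusted p = 0.0606, limma). The call was not made, and camera with an estimated correlation gave p = 0.274 (adjusted p = 0.826). The 1 member past limma when adjusted over the list alone was atp1a1a.4 (adjusted p = 0.0120), with 0 over all probes. The sodium pump subunit atp1a1a.5 had a mean of -4.25 ± 1.66, the anion exchanger slc4a2a -4.00 ± 1.42 and the nephron transcription factor hnf1bb 1.73 ± 0.36. The array medians were -0.51, -0.03 and -0.02, and without replicate 1 the median was -0.06. Over the alternatives camera's adjusted p with limma ran from 0.0132 to 0.826, and with median centring the median was 0.33, below the 0.55 of all tested genes.

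Nephron progenitor regulators, the group the lhx1a label names, had a median of 0.06 over 29 genes, 16 above and 13 below 0 (camera adjusted p = 0.996, limma). The kidney progenitor factor six2a had a mean of 2.30 ± 0.85, hoxa11b -0.75 ± 0.65 and the growth factor fgf20a -1.17 ± 0.14. No member passed limma: 0 over all probes and 0 when adjusted over the list alone, with 0 higher and 2 lower at an unadjusted p under 0.05. The mean of the list was 0.15, and camera's direction was down, so the median and mean differ in sign from the test. Without replicate 1 the median was -0.021.

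The remaining lists were not shifted by camera, and 0 of their members passed limma over all probes or when adjusted over the list alone. Epithelial junction genes had a median of -0.10 over 47 genes (epcam -3.45 ± 1.70, cldn3c -3.46 ± 1.46), Notch genes -0.24 over 17 (notch1a -2.10 ± 0.72, hey1 1.85 ± 0.76), Wnt genes -0.16 over 26 (ctnnb1 -0.95 ± 0.19) and FGF genes 0.03 over 18 (fgfr3 -1.76 ± 1.17). For hey1 and for ctnnb1, 1 of the 2 tested probes had the opposite sign. Podocyte genes had 0.12 over 19, proximal tubule genes 0.02 over 28, stromal genes 0.13 over 31, endothelial genes -0.11 over 22, erythroid genes 0.08 over 20 and interrenal, chromaffin and Stannius genes -0.04 over 16. Cell cycle genes had 0.03 over 63 (chek1 -1.44 ± 0.22), V-ATPase genes -0.06 over 15 and hox genes -0.10 over 40 (hoxd10a 1.86 ± 0.32, hoxb8a -3.91 ± 1.17). Oxidative phosphorylation genes had -0.27 over 54 (ndufs1 1.19 ± 0.17, cox6b2 -4.86 ± 0.77) and ribosomal protein genes -0.25 over 83 (rps13 3.42 ± 0.44, rpl22 -2.57 ± 0.36). Their camera adjusted p with limma ran from 0.343 to 0.883. Median, mean and camera differed in sign for the cell cycle, endothelial, FGF and pan-leukocyte lists. With an estimated correlation camera called none of the lists, neither those of the stress, myeloid and multiciliated genes nor any other (0 lists). By fry, 0 of the 22 lists passed in 1 direction and 6 passed for changes in either direction: the immediate early and stress, distal tubule, pan-leukocyte, Wnt, hox and proximal tubule lists. The myeloid and multiciliated lists that camera called were not among these, with fry adjusted p = 0.0614 and 0.0990 for changes in either direction.

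**Figure D3:**
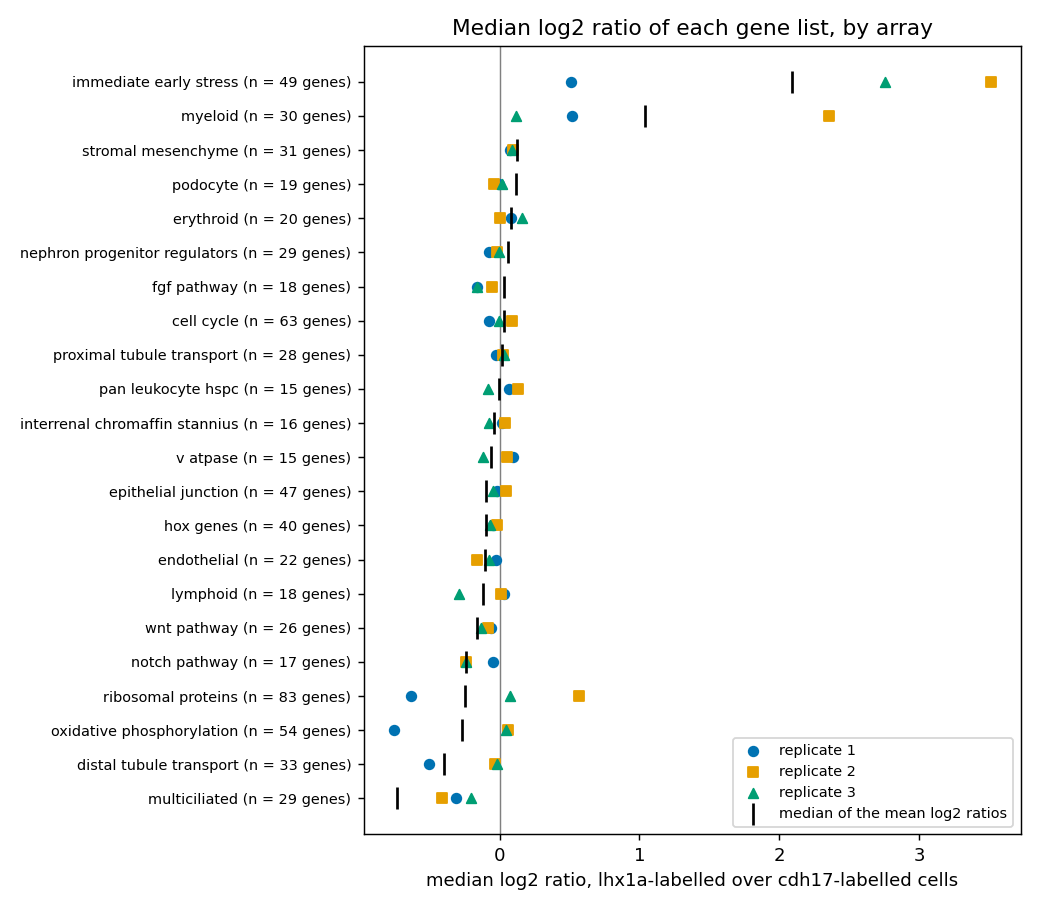
Median log2 ratio of lhx1a-labelled over cdh17-labelled cells (x axis) of each gene list (y axis, with the number of tested genes). Coloured points are the medians on the 3 arrays and black bars the median over genes of the mean log2 ratio; immediate early and stress genes lie at 0.51, 3.51 and 2.76, and the medians of most other lists lie close to 0.

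A set of 1721 probes was well above background on all 3 arrays in the Cy5 channel of the lhx1a-labelled cells and on none in Cy3, against 19 probes in the opposite case. Of the 1721 probes 1559 had a bound above 1-fold and 38 a bound of at least 2-fold, and of the 19 probes 19 and 3 had. The rest of the 1721 probes thus had no higher normalized signal in lhx1a-labelled cells by this bound. The genes with the largest bounds in lhx1a-labelled cells were the ubiquitin-conjugating gene ube2v2 (2.68-fold), chchd3a (2.19-fold), the polycomb gene pcgf6 (2.14-fold), sh3glb2a (2.05-fold) and chmp4c (1.94-fold). For these genes the bound equalled the mean log2 ratio, because the floor on the dim signal had no effect. Their fold values are thus point estimates and not lower limits. On the other side the 1 named gene was ube2g1a (2.84-fold), whose bound was only slightly smaller in size than its mean log2 ratio. For ube2g1a and for ube2v2 limma's adjusted p was 0.711. Without replicate 1, 2 or 3 the Cy5 count was 3664, 3276 and 2930 and the Cy3 count 104, 134 and 126, since 2 arrays then sufficed.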

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

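The spike-in type control spots named E1A, which no comparison used, carried signal above the negative control spots. Of 960 such spots over the 3 arrays, 67.9% were well above background in the Cy3 channel and 91.2% in the Cy5 channel, against 0.87% and 1.09% of 459 negative control spots. The 10 E1A probes had mean log2 ratios from -0.97 to 0.59, and the median SD between arrays was 0.18 for these probes and 0.46 for tested genes. The SDs are not like for like: E1A probes averaged many spots per array without a background filter, while tested genes passed that filter and mostly had 1 spot.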

How the results depend on the processing

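The alternatives below were fixed in advance, except the count of genes beyond 2-fold on every array, which was chosen after seeing the data. The direction of a list was read from its median, and for lists that camera called also from camera. By limma the counts of genes and probes past the threshold stayed at 0 under all 16 and 14 alternatives, with 411 to 1956 genes at an unadjusted p under 0.05. Of the other values, 1515 of single genes and 313 of lists kept their direction and their side of the threshold, and 23 and 29 turned. The remaining list values did not turn, with 6 gaining and 4 losing the call. Part of this was fixed in advance. No named gene was past the threshold under any alternative, and some alternatives leave the log ratios unchanged. The faint signal, with median Cy3 signals of 24.6 to 26.1 over backgrounds of 14 to 14.5, limits what can be measured of weakly expressed genes.

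Median centring turned the direction of 19 named genes and 12 lists, while 84 named genes and 10 lists kept theirs, and under it the median of all genes was 0.548. The sort markers turned too, with means of 0.556 (lhx1a) and 1.235 (cdh17). The named genes that turned were phb2a 0.065, psmd6 0.058, slc25a5 0.791, adgrv1 0.068, chek1 0.231, erg 2.137, fgfr3 0.247, il17rd 0.384, stc1l 0.117, phox2a 0.491, igic1s1 0.044, fgf20a 0.118, hoxa11b 1.215, notch1a 0.177, lmx1ba 0.374, rpl14 0.635, atp6v0e1 0.556, ctnnb1 0.515 and wnt4b 0.46. The list medians that turned were distal tubule 0.334, endothelial 0.377, epithelial junction 0.301, hox 0.526, interrenal, chromaffin and Stannius 0.586, lymphoid 0.231, Notch 0.74, oxidative phosphorylation 0.367, pan-leukocyte 1.145, ribosomal protein 1.772, V-ATPase 0.731 and Wnt 0.458. The myeloid median was 2.769, and camera's call was lost. Camera then called oxidative phosphorylation genes (adjusted p = 0.0168, from there to 0.873 over the alternatives). Their median of 0.367 was above 0 but below the 0.548 of all genes. Some turned values lay above the 0.548 of all genes. These were the sort markers, erg, hoxa11b, slc25a5, rpl14 and atp6v0e1. Among lists they were the ribosomal protein, pan-leukocyte, Notch and V-ATPase lists and that of interrenal, chromaffin and Stannius genes. The other turned values stayed below it. The cause was not tested.

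With an estimated inter-gene correlation 0 lists passed, and the immediate early and stress (2.092), myeloid (1.041) and multiciliated (-0.736) lists were no longer called, while their medians are by construction unchanged. Camera's adjusted p over the alternatives ran from 1.04e-15 to 0.826 for the stress list, from 2.32e-06 to 0.826 for the myeloid list, from 7.09e-05 to 0.826 for the multiciliated list and from 0.0132 to 0.826 for the distal tubule list, whose call was gained in 6 alternatives. The limma adjusted p of the sort markers was over 0.05 in all of them.

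Other medians that turned lay close to 0: the pan-leukocyte list at 0.041 (offset 0), 0.014 (no background correction) and 0.096 (scanner software), the interrenal, chromaffin and Stannius list at 0.049 (scanner software), and the cell cycle and proximal tubule lists at -0.024 and -0.006 (above background on all 3 arrays). With the mean of all probes il17rd was 0.23 and ctnnb1 0.076, since their probes differ in sign. The cause of the others was not tested.

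With each replicate left out in turn, cdh17 ran from -0.97 to 0.478, the distal tubule list from -0.38 to -0.062, ets1 from -0.082 to 2.18 and phox2a from -0.736 to 0.021. The lists that turned were FGF (-0.236 to 0.097), cell cycle (-0.018 to 0.044), interrenal, chromaffin and Stannius (-0.034 to 0.019), lymphoid (-0.149 to 0.06), nephron progenitor (-0.021 to 0.083), oxidative phosphorylation (-0.545 to 0.064), pan-leukocyte (-0.155 to 0.072), proximal tubule (-0.029 to 0.047) and ribosomal protein (-0.692 to 0.115). The cause was not tested. The probes detected in 1 population only ran from 2930 to 3664 (lhx1a-labelled) and from 104 to 134 (cdh17-labelled), and were 3611 and 155 when 2 of 3 arrays sufficed, higher because fewer arrays were asked for. The count of genes beyond 2-fold on every array was 358 with offset 0, 669 with the scanner software's ratio, 905 with median centring and 387 to 509 with 2 arrays.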

Other observations

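Of the tests below, those of spot noise and of genes near background were set before their results were seen, and all others were chosen after seeing the result.

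Several cell type and cell cycle genes had large mean log2 ratios that rested on 2 of the 3 arrays and did not pass limma. The homeobox gene meis1b had a mean of 3.22 ± 1.29 (SE, n = 3), the replication clamp pcna 3.97 ± 1.70 and the matrix gene sparc 2.75 ± 1.30, all higher in lhx1a-labelled cells, with a limma adjusted p = 0.711 for each. The cyclin ccnb3 had a mean of -2.20 ± 0.83 and the epithelial gene prom2 -3.36 ± 1.39. The array values of creg1 were 0.63, 0.83 and 0.73.

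Large ratios mostly stood on a single array. Of 1073 genes with a log2 ratio of at least 4 in size on any array, 907 (84.5%) had it on 1 array only, 483 (45%) lay within 1 of 0 on the other 2, and 10 (0.9%) had it on all 3 with the same sign. Another 65 (6.1%) were extreme both ways. Genes beyond 2-fold the same way on all 3 arrays numbered 159, against 78, 52 and 57 when the sign of replicate 1, 2 or 3 was turned.

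The immediate early and stress genes were weighed against dye bias and leukocytes. In ratios without loess, which keep any trend with intensity, their median was 4.18, at percentile 100 of 10000 random lists matched on intensity whose middle range ran from 1.24 to 2.36, so an intensity-dependent dye bias is unlikely to be the whole cause. The myeloid list was higher too (median 1.04, 24 of 30 genes above 0, camera adjusted p = 8.46e-05 with limma, adjusted p = 0.826 with an estimated correlation), though its median on replicate 3 was 0.12. The pan-leukocyte median was -0.003, 2.09 below that of the stress list, but its 15 members had an SD of 1.38, so carried-over leukocytes remain undecided. The pattern could reflect a difference between the populations, a different response to dissociation and sorting, or a dye effect of single probes, and no dye swap or unsorted sample was available to separate these.

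The low agreement between arrays was weighed against spot noise, faint signal and amplification. Spots of the same probe correlated at 0.987 or more within an array, against 0.465 at most between arrays for the same 31 probes. For these probes spot and scan noise is thus unlikely to be the cause. Over all genes the highest correlation between arrays was 0.115, so the 31 probes may not stand for genes measured by 1 spot. The 2048 genes brightest by the mean of both channels over the arrays correlated at no more than 0.127. Nearness to background in both channels on all arrays is thus an unlikely cause too. A gene near background in 1 channel or on 1 array can still be among these genes, so that case stays undecided. The brightest and next probes of a gene correlated at 0.351, 0.362 and 0.324 within arrays, above 0.136 at most for 1 probe between arrays, which leaves uneven amplification of single fragments undecided. Random loss of transcripts in amplifying few cells and differences between the sorted samples could both give this pattern.

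The probes detected in 1 channel only lay almost all in Cy5, and only 2.21% of them had a bound of at least 2-fold. A higher sensitivity of the Cy5 channel alone would put these probes in Cy5, so they may not be expressed in 1 population only. The small share of bounds of at least 2-fold cannot decide this. The bounds use signals after loess and the normexp offset, which compresses ratios of dim probes, so a difference between the populations could give a small share too. A difference between the populations was not tested, since dye and population coincide.

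Turning the sign of whole arrays makes 4 patterns, too few for a share under 0.05, as a test of whether the arrays line up by chance. As many genes past the threshold came from 4 of the 4 patterns (0 with the real signs by limma, 0 at most with others), and as many lists past camera from 2 of the 4 (3 with the real signs, 3 at most with others, when replicate 3 was turned). At an unadjusted p under 0.05 limma gave 553 genes with the real signs, against 199, 160 and 154 with replicate 1, 2 or 3 turned.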
